A study of Rattus norvegicus with 6 samples.

How the data were processed

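Poly(A) RNA was sequenced from 6 libraries of primary oligodendrocytes, the myelin-forming cells of the central nervous system, cultured from rats at postnatal day 1. Per the labels, 3 libraries came from cells given phosphate-buffered saline (PBS) and 3 from cells given 0.01 mM water-soluble cholesterol, each for 12 h. Groups and replicate numbers were taken from the sample titles. The labels do not state whether the 3 samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The control named in the labels is PBS. Water-soluble cholesterol is commonly supplied as a complex with a cyclodextrin, and a carrier control was not analysed here.

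Per the labels' protocols, libraries were made with a second-strand dUTP method that keeps the strand of the RNA and were read in pairs on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the genome build rn6, without saying what each was used for. The annotation release, and whether counting used the strand, were not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene and FPKM side by side, per the file headers. Across 12526 genes with more than 100 counts in every library, the ratio of the deposited count to the deposited FPKM was fixed for each gene up to 1 factor per library, with a residual SD of 0.001 on the log2 scale. Over the 6 libraries, 2178 values equalled 4 and 1304 equalled 8, against 1307 equal to 3 and 889 equal to 7. Such steps can come from counts derived from transcript coverage, but how the authors made the counts is not recorded in the labels or headers. If they were so derived, the count model only approximates their error.

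Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept (16182 of 20422 genes, with 4240 left out), library sizes were scaled by TMM, and the groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, without a replicate term. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The plan had been written for a file of FPKM alone, with this count test named for the case that counts were also present. Expression levels are TMM-scaled CPM, given as mean ± SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The count and FPKM columns used here belonged to the 6 samples. Every entry had a gene ID, but 2107 entries had no symbol beside it.

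Before the data were examined, 24 gene lists were fixed: 5 primary lists on sterol metabolism and the oligodendrocyte lineage, secondary lists on other pathways, and markers of 5 other cell types. Members were matched by symbol, taking the gene ID with the highest mean FPKM where a symbol had several. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry were run beside it. Fry's directional p tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of members are given over all genes tested and adjusted over the list alone. The rule for named genes, also fixed beforehand, took the 12 genes with the largest log2 fold change in each direction among genes past the threshold whose groups did not overlap, with a mean of at least 1 FPKM and a symbol. It further took up to 4 members of each list with the smallest p (where none passed, the 2 with the highest mean FPKM), and a short set of genes fixed by name, among them Sqle, Insig1, Srebf2, Abca1, Abcg1, Apoe, Mbp, Myrf, Pdgfra and Axin2. Not every gene the rule took is described here. Other members named to spell out a small count were chosen after their values were seen.

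Depth ranged from 63769532 to 70878378 counts per library, at which 3 counts correspond to between 0.0423 and 0.047 CPM. This floor covers counting error only. The method was tested on simulated data for cholesterol against PBS, drawn from the real means and library sizes over 15955 genes. It called 86.9% of 99 genes changed 2-fold and 40.2% of 97 genes changed 1.3-fold, with no wrong sign, and 14 of its calls (10.1%) were of unchanged genes. Small fold changes near the threshold are therefore the least certain calls. Far fewer genes changed in the simulation than were called in the real data, so its share of false calls does not carry over. Of 200 simulated lists without a change, 0.5% had a camera p under 0.05 with the preset correlation. Simulated genes were drawn independently, so this share does not apply to lists whose genes vary together.

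The alternatives fixed before the data were examined were no filter on low values, a mean of at least 5 FPKM, DESeq2 1.42.0 size factors in edgeR, scaling to the library median, quantile normalization with limma voom, the DESeq2 Wald test, the replicate number as a block, and leaving out each library in turn. Those written for a file of FPKM alone were not run as planned. Chosen after seeing the data were a correction for transcript length, the deposited FPKM tested with limma at pseudocounts of 1 and 0.1 (mean of at least 1 FPKM), leaving out the 20 most abundant genes, and a test of the KEGG pathways that the deposited table assigns to genes (10 to 300 tested members). Fold changes in the FPKM tests are on the scale of log2 of the FPKM plus the pseudocount and understate the changes of low genes. For the length correction, log2 CPM was taken less each gene's mean over all libraries. Each library's smooth trend of these values on transcript length was removed, with length derived from the ratio of count to FPKM. For lists and pathways it was first run by camera on the corrected log2 CPM, and then, after those values had been seen, on the counts with the trend as an offset, to match the statistic used elsewhere. Results of both are given. Overlaps between genes were taken from the start and end positions in the deposited table, without exons or strands, so an overlap need not mean shared exons. Figures were drawn with matplotlib 3.10.9.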

Results

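The transcriptomes of primary rat oligodendrocyte cultures were compared after 12 h with 0.01 mM water-soluble cholesterol or with PBS, with 3 libraries per group. The title of the series places the experiment in work on brain cholesterol balance and myelin formation, and the comparison asks which transcripts change when these cells are given cholesterol. The PBS libraries held 70878378, 69031040 and 68902794 counts and the cholesterol libraries 63874804, 67656224 and 63769532, assigned to 20422 genes, of which 17486 were protein coding. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 8.85 to 10.04 between PBS libraries and 14.34 to 20.87 between cholesterol libraries. Pairs from different groups lay at 83.29 to 114.16. The first principal component of log2 CPM held 42.8% of the variance and separated the groups, with PBS libraries between -33.5 and -32.2 and cholesterol libraries between 27.9 and 37.2.

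After cholesterol, most enzymes of cholesterol synthesis fell, and most myelin genes and nearly all of the 24 listed cell cycle genes rose. Most microglial markers fell and most astrocyte markers rose in the same libraries. Of 16182 genes tested with edgeR's quasi-likelihood test, 3325 were higher and 3189 lower after cholesterol, 40.3% of the total, and 9668 did not pass an adjusted p of 0.05. A change of at least 2-fold was seen in 349 of the higher and 234 of the lower genes, or 154 and 112 among those with a mean of at least 1 FPKM. The 3 cholesterol values lay entirely above or below the 3 PBS values for 52.3% of genes, against 10% by chance. The split between directions depended on scaling, since scaling each library to its median gave 2517 higher and 4158 lower genes, 37.7% higher against 51% with TMM, and moved the median log2 fold change of all genes from 0.0053 to -0.0564.

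Enzymes of cholesterol biosynthesis fell almost as a block. Of the 21 enzymes tested, 18 were lower and 0 higher (19 lower adjusted over the list alone), 16 of them by at least 2-fold, with a median log2 fold change of -1.09. Hmgcs1, an enzyme early in the mevalonate pathway, fell from 1039 ± 5.19 to 391 ± 23.3 CPM (SD, n = 3 per group), a log2 fold change of -1.41 ± 0.043 (SE, adjusted p = 1.37e-07). Sqle, which oxygenates squalene, fell from 328 ± 3.76 to 132 ± 7.08 CPM (-1.32), and the demethylating enzymes Cyp51 and Msmo1 by 1.17 and 1.34 on the log2 scale. Pmvk (-0.19), Lbr (-0.06) and Ebp (-0.01) did not pass the test over all genes. Camera gave the list an adjusted p of 1.31e-77, which became adjusted p = 0.0542 with an estimated correlation. Idi1, Fdps, Mvd and Hsd17b7 each overlap 1 other annotated gene, so their counts are less certain, because use of the strand in counting is not stated.

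Sterol sensing and uptake genes were mostly lower. Of 17 tested, 10 were lower and 2 higher (10 and 2 adjusted over the list alone), with a median log2 fold change of -0.18. Insig1, a sterol-dependent brake on SREBP processing, fell from 397 ± 1.86 to 138 ± 14.7 CPM, a log2 fold change of -1.52 ± 0.064 (SE, adjusted p = 2.07e-07). Stard4, a cytosolic sterol carrier, fell from 35.9 ± 0.455 to 12.1 ± 1.78 CPM (-1.57), and Srebf2, which encodes the SREBP of sterol synthesis, by 0.75 on the log2 scale. The 2 genes that rose were Srebf1 (36.6 ± 0.959 to 76.4 ± 3.85 CPM, log2 fold change 1.06), which overlaps 1 other gene, and Insig2 (0.60). Npc2, Npc1, Scap, Lipa and Vldlr did not pass. Camera gave an adjusted p of 2.48e-05 for a fall of the list, with adjusted p = 0.319 with an estimated correlation, and the call was also lost under quantile normalization (adjusted p = 0.0687).

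Targets of the liver X receptors and genes of sterol efflux, oxidation and esterification went both ways. Of 18, 7 were higher and 5 lower (7 and 5 adjusted over the list alone), the median log2 fold change was -0.07 and the mean 0.02, and camera gave no call (adjusted p = 0.495, direction up). The counts were 6 higher and 3 lower without PBS replicate 3 (median -0.05) and 7 and 8 without cholesterol replicate 2 (-0.18), and the median was -0.03 without PBS replicate 2, 0.07 without cholesterol replicate 1 and -0.01 without cholesterol replicate 3. Abca1, the main cholesterol exporter to lipid-poor apolipoproteins, rose from 95.5 ± 5.24 to 148 ± 9.77 CPM, a log2 fold change of 0.64 ± 0.055 (SE, adjusted p = 1.52e-05). Abca2 (0.42), Abcg4 (0.73) and Soat1, which esterifies cholesterol for storage (0.30), also rose. Abcg1, another exporter, fell from 73.7 ± 4.71 to 58.4 ± 7.46 CPM (log2 fold change -0.33, adjusted p = 0.00824). Apoe, the main lipid carrier of the brain, stood at 1274 ± 49.7 and 1266 ± 190 CPM, a difference within the spread of replicates (log2 fold change -0.01 ± 0.084, adjusted p = 0.942). Without cholesterol replicate 2 its log2 fold change was -0.13, with an adjusted p of 0.0474. Microglial markers fell in the same libraries (median log2 fold change -0.61), and which cells account for the Abcg1 and Apoe values was not tested.

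Fatty acid synthesis genes were lower more often than higher. Of 18, 9 were lower and 4 higher (11 and 4 adjusted over the list alone), with a median log2 fold change of -0.14 but a mean of 0.10. Fasn fell from 1130 ± 35.1 to 672 ± 37.2 CPM (log2 fold change -0.75), Acly by 0.72 and Acaca by 0.69 on the log2 scale, and Acly and Acaca overlap 2 and 1 other genes. The mean was raised by Thrsp, a regulator of lipogenesis, which had the largest rise among named genes, from 0.299 ± 0.145 to 4.80 ± 0.458 CPM (log2 fold change 4.0 ± 0.283, SE, adjusted p = 5.05e-06). The other 3 genes that rose were Gpam (0.43), Me1 (0.51) and Elovl1 (0.25). Camera called a fall of the list (adjusted p = 0.0165) that did not hold with an estimated correlation (adjusted p = 0.547) or under quantile normalization (adjusted p = 0.0766).

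**Figure D1:**
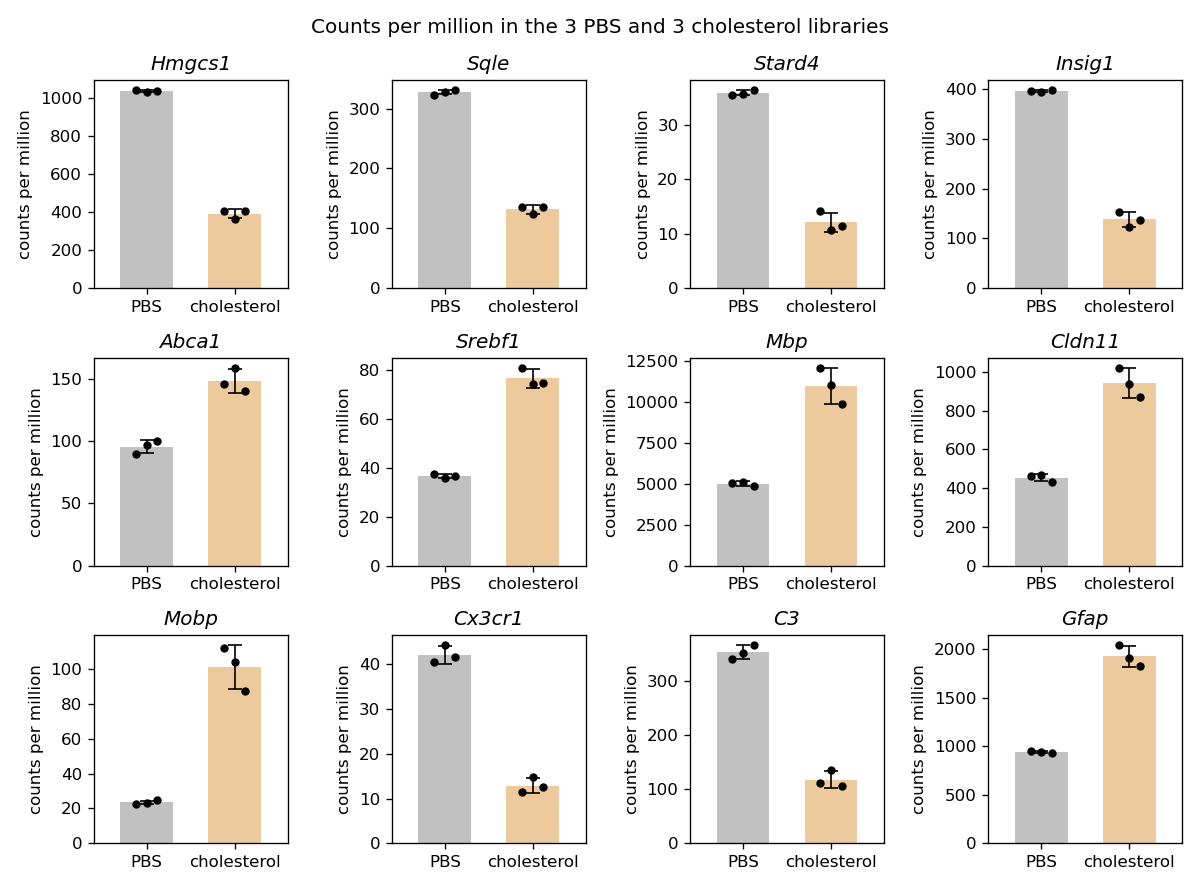
TMM-scaled CPM (vertical axis, from 0) of 12 genes with PBS and with cholesterol; bars give the mean of 3 libraries, error bars the SD and points the libraries. Hmgcs1, Sqle, Stard4, Insig1, Cx3cr1 and C3 lay lower in all 3 cholesterol libraries than in any PBS library, and Abca1, Srebf1, Mbp, Cldn11, Mobp and Gfap lay higher.

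Myelin and mature oligodendrocyte genes rose. Of 25, 21 were higher and 3 lower (22 and 3 adjusted over the list alone), 13 rose at least 2-fold, and the median log2 fold change was 1.04, or 0.65 (15 higher and 3 lower) among members with a mean of at least 5 FPKM. Mbp, a structural protein of compact myelin, rose from 5003 ± 142 to 10980 ± 1100 CPM, a log2 fold change of 1.13 ± 0.059 (SE, adjusted p = 9.38e-07). Cldn11, which forms the tight junctions of myelin, rose from 454 ± 17.8 to 943 ± 76.7 CPM (1.06), and Mobp from 23.5 ± 0.980 to 101 ± 12.6 CPM (2.1). The 3 members that fell were Enpp2 (-0.60), Fa2h (-0.24) and Ugt8 (-0.13), the last pair being enzymes of myelin galactolipid synthesis, and Cnp (0.08) did not pass. Myrf, the transcription factor that drives myelin genes, rose little, from 717 ± 14.8 to 797 ± 56.3 CPM (log2 fold change 0.15, adjusted p = 0.0258). Its call ended without PBS replicate 1, 2 or 3 (adjusted p = 0.0768, 0.103 and 0.0609), without cholesterol replicate 1 (0.0940) and with scaling to the library median (0.170). Camera gave the list an adjusted p of 5.66e-21, with adjusted p = 0.120 with an estimated correlation. Astrocyte markers rose in the same libraries, with a median log2 fold change of 0.66.

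Genes of earlier lineage stages showed no common direction. Of 15 precursor genes, 4 were higher and 7 lower (4 and 7 adjusted over the list alone), with a median log2 fold change of -0.05 and a camera adjusted p of 0.405. The median was -0.01, -0.14 and -0.14 without PBS replicates 1, 2 and 3, and -0.08 and -0.02 without cholesterol replicates 2 and 3. Sox6, a transcription factor of precursors, fell from 126 ± 3.22 to 72.3 ± 5.39 CPM (-0.81) and the matrix proteoglycan Vcan from 977 ± 16.7 to 601 ± 70.3 CPM (-0.70). Cspg5 (0.77) and Hes5, a Notch target (1.01), rose, as did Cspg4 (0.26). Pdgfra, the growth factor receptor that marks precursors, was at 323 ± 4.62 and 342 ± 19.7 CPM (log2 fold change 0.08, adjusted p = 0.155), but passed without cholesterol replicate 2 (0.13, adjusted p = 0.0138), under quantile normalization (adjusted p = 0.0495) and with the length correction (0.18, adjusted p = 0.00272). Of 11 committed precursor and premyelinating genes, 5 were higher and 5 lower (the same counts adjusted over the list alone; median -0.07, mean 0.04, camera adjusted p = 0.893), among them Rras2 (0.96) and Enpp6 (0.46) upward and Bcas1 (-0.35), which overlaps 2 other genes, and Tnr (-0.39) downward. Scaling to the library median gave 3 higher and 6 lower in that list, and its median was -0.04 without cholesterol replicate 2 and -0.11 without cholesterol replicate 3. Of 12 lineage transcription factors, 5 were higher and 3 lower (5 and 4 adjusted over the list alone; median -0.04, mean 0.06, camera adjusted p = 0.957). Nkx6-2 rose (1.04), while Nkx2-2 (-0.56), Olig2 (-0.35) and Zeb2 (-0.24) fell. The balance of this list turned to 3 higher and 7 lower with scaling to the library median and 5 and 6 with the length correction, and was 3 and 3 without PBS replicate 1, 2 or 3 or without cholesterol replicate 1. Its median was -0.03 without cholesterol replicate 2 and 0.01 under quantile normalization.

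The listed cell cycle and DNA replication genes rose together. Of 24, 21 were higher and 0 lower (the same adjusted over the list alone), none by 2-fold, with a median log2 fold change of 0.58. Top2a, the topoisomerase of dividing cells, rose from 102 ± 3.11 to 184 ± 3.17 CPM (0.85 ± 0.037, SE, adjusted p = 2.57e-07), Cdk1, the mitotic kinase, from 23.6 ± 0.243 to 44.3 ± 1.42 CPM (0.91), Ccnb1 by 0.73 and Kif11 by 0.65. Mcm4 (0.13), Mcm7 (0.03) and E2f1 (0.08) did not pass. Camera gave an adjusted p of 8.60e-17. This was the one list of the 24 whose call held with an estimated correlation (adjusted p = 0.0164). Its estimate was negative (-0.0296), below the preset 0.01, so its call did not have to withstand a larger correlation. A negative estimate did not by itself keep a call. The list of endoplasmic reticulum and integrated stress responses had an estimate of -0.0151 and lost its camera call (adjusted p = 0.120). The estimates for the myelin and cholesterol synthesis lists were 0.297 and 0.599.

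Nuclear genes of oxidative phosphorylation rose by small amounts, 20 of 25 higher and 0 lower (21 and 0 adjusted over the list alone), with a median log2 fold change of 0.19 and a camera adjusted p of 2.20e-04 (adjusted p = 0.547 with an estimated correlation). The number of higher genes was 12 without PBS replicate 1, without PBS replicate 2 and with scaling to the library median, and 13 with a correction for transcript length, which lowered the median to 0.11. Atp5mc1 (0.48), Ndufa4 (0.35) and Cox7c (0.31), which overlap 1 other gene each, and Ndufv1 (0.21) were the named members. The Atp5mc1 entry is labelled a long non-coding RNA in the deposited table. Of 13 mitochondrially encoded genes, 8 were higher and 0 lower (the same adjusted over the list alone; median 0.14, camera adjusted p = 0.00624, adjusted p = 0.319 with an estimated correlation), including Mt-co2 (0.24), Mt-co3 (0.32), Mt-atp6 (0.25) and Mt-atp8 (0.29). The last 3 overlap neighbouring genes. The call for this list was lost with the length correction, chosen after seeing the data (adjusted p = 0.366; 5 higher and 1 lower, median 0.04), and scaling to the library median gave 7 higher and 1 lower with a median of 0.08. Across 12432 genes, fold change fell with transcript length, from a median of 0.11 in the shortest decile to -0.14 in the longest, and genes are not independent replicates. Of 19 hypoxia and glycolysis genes, 7 were higher and 3 lower (8 and 3 adjusted over the list alone; median 0.12, camera adjusted p = 0.0582, or 0.0163 without cholesterol replicate 3). Ndrg1 (1.69) and the glucose transporter Slc2a1 (0.60) rose most clearly, Tpi1 rose (0.32) and Hk2, hexokinase, fell (-0.51) along with Vegfa (-0.48) and Pkm (-0.11).

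Inflammatory genes were lower more often than higher, 8 against 3 of 17 (9 and 3 adjusted over the list alone), with a median log2 fold change of -0.46. C3, the central complement component, fell from 354 ± 12.8 to 118 ± 16.3 CPM (-1.58 ± 0.080, SE, adjusted p = 7.36e-07), and Tnfaip3, an inhibitor of NF-kappaB signalling, from 22.7 ± 0.965 to 11.3 ± 1.10 CPM (-1.0). Vcam1 (1.14), Lcn2 (0.91) and Il1a (0.65) rose. The counts of lower and higher genes were 4 and 2 without PBS replicate 1 or PBS replicate 2, 5 and 2 without cholesterol replicate 1, and 5 and 3 without cholesterol replicate 3 (median -0.30) or without a filter. Camera gave an adjusted p of 0.0184, against 0.0644 without cholesterol replicate 3 and adjusted p = 0.547 with an estimated correlation. Microglial markers fell in the same libraries, with a median of -0.61. Of 16 interferon-stimulated genes, 5 were lower and 0 higher (the same adjusted over the list alone; median -0.37), namely Gbp2 (-0.77), Usp18 (-1.08), Stat2 (-0.24), Ifi27 (-0.54) and Mx1 (-0.74). Camera did not call that list (adjusted p = 0.0825), but did so without PBS replicate 1 (adjusted p = 0.0195), and its median was -0.56 without cholesterol replicate 2.

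Of 19 genes of endoplasmic reticulum and integrated stress responses, 6 were lower and 0 higher (the same adjusted over the list alone; median -0.17, camera adjusted p = 0.00168, adjusted p = 0.120 with an estimated correlation). Scaling to the library median gave 11 lower. The 6 included the chaperones Calr (954 ± 28.4 to 610 ± 21.9 CPM, -0.65) and Hsp90b1 (-0.45), the transcription factor Atf4 (-0.34) and Edem1 (-0.65). Over all tested genes, 40.3% passed in either direction. The calls in this list, and in the interferon, immediate early and lysosome lists, made up a smaller share of their members. Oxidative stress and heat shock genes moved both ways, 4 of 15 higher and 5 lower (5 and 5 adjusted over the list alone; median -0.07, mean 0.10, camera adjusted p = 0.893). The median turned to 0.05 without PBS replicate 2 and was -0.16 without PBS replicate 3, -0.01 without cholesterol replicate 1 and -0.20 without cholesterol replicate 3. Nqo1, a quinone reductase, rose from 7.57 ± 1.08 to 27.8 ± 4.19 CPM (1.88) and Hspb1 rose (1.09), while Mt1, a metallothionein, fell (-1.14) with Hsph1 (-0.37). Of 11 immediate early genes, 3 were lower and 0 higher (the same adjusted over the list alone; median -0.26), Egr1 (-1.07), Nr4a1 (-0.57) and Jun (-0.13). The call for Jun ended without PBS replicate 1 (adjusted p = 0.110) or cholesterol replicate 3 (0.0562), under quantile normalization (0.0952) and with the length correction (0.118). Camera did not call that list (adjusted p = 0.0674), but did so without cholesterol replicate 1 (adjusted p = 0.0490). Of 21 lysosome and lipid droplet genes, 6 were higher and 0 lower (the same adjusted over the list alone; median 0.09), among them Hexa (0.48), Cd63 (0.43, overlapping 3 other genes), Lamp1 (0.27) and Gpnmb (0.50). Camera did not call that list (adjusted p = 0.0582), but did so without PBS replicate 2 (0.0467), cholesterol replicate 1 (0.0230) or cholesterol replicate 3 (0.0142). Its median was 0.02 without PBS replicate 3, 0.13 without cholesterol replicate 1 and 0.01 without cholesterol replicate 2, where 7 were higher and 2 lower. The wider KEGG lysosome pathway leaned the other way, with 23 of 120 genes higher and 37 lower, and was not called (camera adjusted p = 0.733). Of 14 Wnt target genes, 2 were higher and 4 lower (the same adjusted over the list alone; median -0.25, camera adjusted p = 0.104, fry adjusted p = 0.0172), with a median of -0.14 without PBS replicate 2. Myc (-0.67), Tnfrsf19 (-0.51), Ccnd1 (-0.26) and Znrf3 (-0.27) fell, Rnf43 (0.51) and Nkd2 (0.43) rose, and Axin2, a widely used readout of the pathway, was at 6.96 ± 0.857 and 5.68 ± 0.704 CPM (-0.29, adjusted p = 0.112).

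Markers of other cell types that a brain culture could hold were measurable in both groups. Summed FPKM of the astrocyte markers was 573 to 580 in the PBS libraries and 813 to 876 in the cholesterol libraries. That of the microglial markers was 262 to 279 and 175 to 236, against 5656 to 5787 and 8509 to 9629 for the myelin genes. Gfap, with a mean of 397 FPKM over the 6 libraries, dominated the astrocyte sum, so its rise mostly follows that gene. Aldoc, with a mean of 182 FPKM, fell. Of 12 astrocyte markers, 9 were higher and 2 lower (10 and 2 adjusted over the list alone; median 0.66, or 0.32 among members with a mean of at least 5 FPKM, camera adjusted p = 4.47e-06, adjusted p = 0.229 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose from 942 ± 9.67 to 1924 ± 109 CPM (1.03 ± 0.040, SE, adjusted p = 1.73e-07), Aqp4 by 0.71 and the glutamate transporter Slc1a2 by 1.14, whereas Aldoc (-0.38) and Fgfr3 (-0.44) fell and Slc1a3 (0.11) did not pass. Of 14 microglial markers, 9 were lower and 1 higher (9 and 2 adjusted over the list alone; median -0.61, camera adjusted p = 5.51e-05, adjusted p = 0.547 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell from 42.1 ± 1.97 to 12.9 ± 1.77 CPM (-1.70), and the complement genes C1qa (-0.81), C1qb (-0.76) and C1qc (-0.68) fell. Trem2 rose (0.41), and Cd14 (0.33), P2ry12 (-0.31), Tyrobp (-0.22) and Cd68 (0.05) did not pass. Neuronal markers (0 higher and 1 lower of 13, camera adjusted p = 0.893), with Map2 lower (-0.46), fibroblast and mural markers (2 and 2 of 9, adjusted p = 0.957; mean 0.01, camera direction down) and endothelial markers (1 and 1 of 6, adjusted p = 0.893; median -0.03, mean 0.03, with a median of 0.02 without PBS replicate 3, -0.01, -0.24 and 0.16 without cholesterol replicates 1, 2 and 3) were not called, and these counts were the same adjusted over the list alone. In the last pair of lists, Dcn (0.65), Pdgfrb (0.66) and Cdh5 (1.47) were higher and Acta2 (-1.32), Col1a1 (-0.30) and Pecam1 (-1.15) lower, all with a mean CPM under 10 except Col1a1. The call ended without PBS replicate 3 for Pdgfrb (adjusted p = 0.0508), Cdh5 (0.128), without PBS replicate 1 for Col1a1 (0.129) and Cdh5 (0.134), and without PBS replicate 2 for Col1a1 (0.181). It also ended without cholesterol replicate 1 for Col1a1 (0.131) and Cdh5 (0.136), without cholesterol replicate 2 for Pdgfrb (0.0509), Cdh5 (0.108) and Col1a1 (0.130), and without cholesterol replicate 3 for Cdh5 (0.0508). Cdh5 and Col1a1 also lost their calls without a filter (0.0551 and 0.0746) and with the replicate number as a block (0.0545 and 0.0693), and Col1a1 under quantile normalization (0.0663), with the length correction (0.109) and on deposited FPKM (0.0803 and 0.0805).

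The 12 largest rises by the fixed rule were those of Thrsp, Ppp1r14a, Efhd1, Gsta1, Aadat, Inmt, Mobp, Pde9a, Aldh1a1, Opalin, Ddah2 and Gng14, with log2 fold changes from 4.0 down to 1.95. Mobp, Opalin and Ppp1r14a belong to the myelin list. Opalin, a membrane protein of mature oligodendrocytes, rose from 5.06 ± 1.61 to 19.8 ± 2.73 CPM, and Gsta1, a glutathione transferase, from 2.73 ± 0.631 to 13.7 ± 0.869 CPM. Aldh1a1, which makes retinoic acid, rose from 2.04 ± 0.226 to 8.23 ± 0.937 CPM. Ppp1r14a (0.167 ± 0.148 to 1.74 ± 0.0694 CPM) had no counts in PBS replicate 3, and Ddah2, at 5.85, 2.14 and 2.03 CPM in the cholesterol libraries, overlaps 1 other gene. Among the 12 largest falls were those of Ccn1, Il10, Ccn2, Cx3cr1, Ptger4, Trpc6, C3, Hsd17b7, Siglec10, Spic and Stard4, with log2 fold changes from -2.06 to -1.57. Ccn1 fell from 7.74 ± 0.149 to 1.86 ± 0.729 CPM (-2.06 ± 0.249, SE, adjusted p = 1.24e-04) and Ccn2 from 5.82 ± 0.939 to 1.5 ± 0.301 CPM (-1.95). Both encode matricellular proteins. The anti-inflammatory cytokine Il10 fell from 2.55 ± 0.184 to 0.645 ± 0.237 CPM (-1.98). Cx3cr1 belongs to the list of microglial markers, whose median log2 fold change was -0.61. Which cells of the culture account for the falls of Il10 and the other immune genes was not tested.

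**Figure D2:**
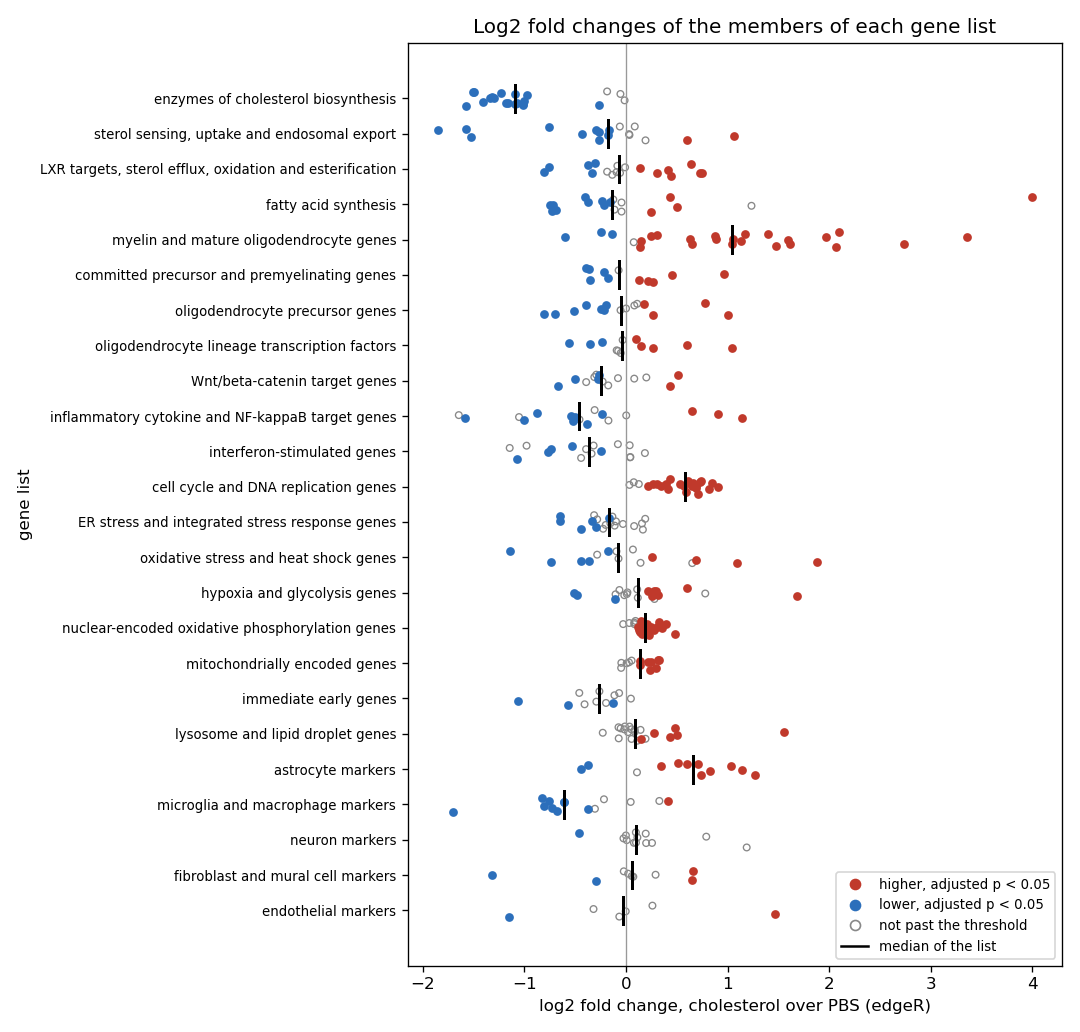
Log2 fold change of cholesterol over PBS (horizontal axis) for each tested member of the 24 gene lists (vertical axis); filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and black lines mark list medians. The medians ran from -1.09 for enzymes of cholesterol biosynthesis to 1.04 for myelin genes, with 0.58 for cell cycle genes, 0.66 for astrocyte markers and -0.61 for microglial markers.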

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

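The 24 lists, the counts of calls and 115 named genes were recomputed under each alternative. The length corrections, the tests on deposited FPKM and the run without the 20 most abundant genes were chosen after seeing the data. The numbers of higher and lower genes stayed within 1.5 times in every alternative (2396 to 3393 higher and 2324 to 4158 lower), and leaving out 1 library gave 2629 to 3205 higher and 2467 to 3129 lower. Of the 115 named genes, 106 kept their direction and side of the threshold in every run that tested them, and the other changes were 29 calls lost, 4 gained and 1 change of sign, that of Mt-co3, whose log2 fold change under quantile normalization was 0 after rounding. The 583 genes changed at least 2-fold became 113 with a mean of at least 5 FPKM, where low genes are not tested, and 125 and 264 on the deposited FPKM with pseudocounts of 1 and 0.1, where genes with a mean under 1 FPKM are not tested. Among genes with a mean of at least 1 FPKM, the count test gave 154 higher and 112 lower by 2-fold, so the smaller gene set goes with most of the difference for the pseudocount of 0.1. The deviations of same-numbered libraries showed no correlation (0, -0.04 and -0.03), and not every library correlated best with its own number. With 3 libraries per group this does not exclude a pairing by culture or animal, on which the labels are silent. The replicate block gave 3165 higher and 3056 lower genes, and its camera adjusted p for the lysosome and lipid droplet list was 0.0318, past the threshold, while Cdh5 (0.0545) and Col1a1 (0.0693) lost their calls. With a mean of at least 5 FPKM, fewer members are tested, and the higher and lower counts were 15 and 3 for myelin (median 0.65), 4 and 2 for astrocyte markers (median 0.32), 0 and 5 for inflammation, 0 and 2 for interferon, and 4 and 5 for liver X receptor targets. Rescaling FPKM to TPM, a fit without the intensity trend and robust variances were written for a file of FPKM alone and were not run. At 63769532 to 70878378 counts per library, 3 counts correspond to 0.0423 to 0.047 CPM, below which values are not read.

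With an estimated correlation, camera calls were lost for cholesterol synthesis (0.0542), sterol uptake (0.319), fatty acid synthesis (0.547), myelin (0.120), inflammation (0.547), stress responses of the endoplasmic reticulum (0.120), oxidative phosphorylation (0.547), mitochondrially encoded genes (0.319), astrocyte (0.229) and microglia markers (0.547). The estimate rests on few residual degrees of freedom from 6 libraries. In the simulation, a changed list had a camera p of 2.74e-71 with the preset correlation and 4.09e-05 with an estimated one. Its genes were drawn independently, so the estimated form gave a weaker result there without correlation between genes. Under quantile normalization, calls were lost for sterol uptake (0.0687), fatty acid synthesis (0.0766) and, by construction, mitochondrially encoded genes (0.143), and gained for interferon (0.0187), hypoxia and glycolysis (0.0239), immediate early (0.0386) and lysosome genes (0.00906). Without a filter, calls were gained for hypoxia (0.0266), immediate early (0.0481) and lysosome genes (0.0285). Fry called the Wnt (0.0172), interferon (0.0421), hypoxia (0.0238) and immediate early lists (8.61e-04). With the length correction as an offset, the mitochondrial call was lost (0.366) and the interferon call gained (0.0479). With it on log2 CPM, calls were lost for sterol uptake (0.0785), fatty acids (0.146) and mitochondrial genes (0.427), and gained for interferon (0.0128) and immediate early genes (0.0311). On deposited FPKM, sterol uptake (0.0515 and 0.0602 with pseudocounts of 1 and 0.1) and fatty acids (0.0747 and 0.0745) lost theirs, and without the 20 most abundant genes the mitochondrial list did (0.136), with a median of 0.15 for its other members. Most mitochondrially encoded genes are themselves among those 20, and quantile normalization gives the top ranks the same values in every library, so neither run tests that list. Leaving out 1 library gave camera adjusted p of 4.11e-04 to 0.0644 for inflammation, 0.0195 to 0.205 for interferon, 0.0163 to 0.118 for hypoxia, 0.0490 to 0.181 for immediate early and 0.0142 to 0.127 for lysosome genes. Over all alternatives the ranges were 2.01e-99 to 0.0542 for cholesterol synthesis, 6.21e-28 to 0.120 for myelin and 5.07e-08 to 0.319 for sterol uptake. Where no construction of the alternative is named, the cause was not tested.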

Other observations

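Apart from the splits of the libraries, the pathway tests and the tests of explanations were chosen after the results they follow had been seen. Of these, the tests of lineage share, of oligodendrocyte dilution, of one factor for each cell type, of overlapping genes and of the slopes on length were also written after the values they use had been seen.

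Among 320 KEGG pathways tested with camera, 44 passed with the preset correlation and 0 with an estimated one (23 at an unadjusted p under 0.05, smallest adjusted p = 0.609), so these are leads only. DNA replication rose, with 23 of 34 genes higher and 1 lower (adjusted p = 3.21e-05), as did mismatch repair, with 13 of 21 higher and 0 lower (adjusted p = 0.00118). The wider cell cycle pathway rose less evenly, with 65 of 151 genes higher and 27 lower (median log2 fold change 0.12, adjusted p = 0.00702). Metabolism of xenobiotics by cytochrome P450 rose with 17 of 34 genes higher and 1 lower (adjusted p = 0.00162), and retinol metabolism with 11 of 25 higher and 1 lower (adjusted p = 0.00828), groups to which the strongly raised Gsta1 and Aldh1a1 are related by function. Ribosome biogenesis fell, with 29 of 73 genes lower and 6 higher (adjusted p = 0.0064), beside the lower Myc, a known driver of that programme. Several immune pathways fell, such as natural killer cell cytotoxicity (31 of 65 lower and 6 higher, adjusted p = 9.59e-04) and Toll-like receptor signalling (30 of 67 lower and 6 higher, adjusted p = 0.0269). In the same libraries microglial markers were lower (median log2 fold change -0.61). Steroid biosynthesis fell with an adjusted p of 5.02e-26. With the length trend removed it stood at 1.37e-28 by the offset and 3.76e-04 on log2 CPM, while Toll-like receptor signalling lost its call by the offset (0.0535) and stood at 0.0466 on log2 CPM. The other pathways named here passed with both forms, retinol metabolism at 0.0148 and 0.0469.

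The rise of myelin genes (median log2 fold change 1.04, or 0.65 with a mean of at least 5 FPKM) was set against a pair of technical explanations and a change in cell share. A larger share of oligodendrocyte lineage cells would raise the genes of the whole lineage alike. The median of Olig1, Olig2, Sox10 and Sox8 was -0.062, below the myelin median by 1.10 with an SE of 0.268. This argues against a larger share as the whole cause. The lineage median rests on few genes, and genes of a list are not independent (estimated correlation 0.297 for the myelin list), which the SE may not cover. With the length trend removed the myelin median was 0.922 (camera adjusted p = 8.42e-22 by the offset and 9.31e-08 on log2 CPM), which argues against the length trend as the whole cause. Leaving out the 20 most abundant genes gave 1.059 but moved nearly all other genes by the same 0.0042 on the log2 scale, so that run does not test whether a few genes took most of the counts. An effect of the cholesterol itself or of its carrier, and a mix of altered share with lower lineage factors, stay open and untested, and the list's call was lost with an estimated correlation (adjusted p = 0.120).

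Astrocyte markers rose (median 0.66, or 0.32 with a mean of at least 5 FPKM) while microglial markers fell (median -0.61). A lower share of oligodendrocyte lineage cells alone would raise both alike, but the medians differed by 1.264 (SE 0.268). With the length trend removed they differed by 1.296 (SE 0.263). These values argue against dilution and against the length trend as the whole cause. Dilution combined with other changes in cell numbers was not tested. Genes of these lists are not independent (estimated correlation 0.22 for astrocyte and 0.656 for microglial markers), which these SEs may not cover. Loss of microglia by one factor for all their transcripts would give markers equal fold changes within error, but they spread more (Cochran's Q of 371.6 over 14 markers, chi-square p = 2.21e-71), with the abundant Tyrobp at -0.22, Ctss at -0.61 and Cd68 at 0.05. The astrocyte markers spread likewise (Cochran's Q of 983 over 12 markers, chi-square p = 8.78e-204), with the abundant Gfap at 1.03 and Aldoc at -0.38, though both p-values rest on standard errors from 3 libraries per group and treat genes as independent. With 40.3% of all tested genes past the threshold, a list could spread beyond such errors whatever its cell numbers did. The spread therefore does not decide whether microglia were lost or astrocytes gained. Altered expression within these cells, alone or together with a change in their numbers, may contribute and was not tested apart, and Sox9 of the astrocyte list is also in the list of lineage transcription factors.

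At 18 genes the count was 0 in at least 1 library and 200 or more in another. By gene spans in the deposited table, without exons or strands, all 18 overlap another annotated gene, against 25.7% of 12539 other genes with 200 or more counts in a library (one-sided Fisher's exact p = 2.41e-11), which is consistent with reads being assigned to one or the other of overlapping genes. Fam181b, for example, had 2710 counts in PBS replicate 2 and 2907 in cholesterol replicate 3 and 0 in the other 4 libraries, so it does not follow the treatment. Fam181b was singled out after its values were seen. No biological explanation was tested.

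Fold change fell with transcript length (Spearman's rho -0.236 across 12432 genes, which are not independent). Slopes on log2 length were taken of log2 CPM less each gene's mean over all libraries, so their signs are relative. They were 0.0136 to 0.0249 in the PBS libraries and -0.0323 to -0.0114 in the cholesterol libraries. The groups did not overlap, with a gap of 0.025 against a largest SD within a group of 0.011. That gap did not reach 3 times that SD, a bound set after the slopes had been seen. The bound therefore does not settle whether the trend follows the groups.

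Ccn1 and Ccn2, both classical targets of YAP and TAZ, were among the largest falls, and lower activity of these regulators was tested as a hypothesis on 20 other targets listed before their values were seen. Of the 19 tested, 5 were higher and 5 lower, with a median log2 fold change of 0.02, and camera gave p = 0.9091 with an estimated correlation, direction up. The wider list did not fall, which does not exclude a response limited to a few targets.

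The 6 libraries can be split into 3 and 3 in 10 ways. The real split called 6514 genes and the highest of the others 2, and the real one was the 1 split with as many. With 10 splits a share under 0.05 cannot be reached.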
